A study of Mus musculus with 2 samples.

How the data were processed

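The data were gene by barcode matrices of 2 droplet libraries, made with 10x Chromium 3' v2 chemistry from intestines of E18.5 embryos on the C57BL/6 background. The labels give whole intestine in 1 place and small intestine as the source in another, so the gut region is not settled. Tissue was dissociated in 0.5 mL papain for 30 min, and about 10000 cells were loaded per library. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, per the labels and as checked by their being whole numbers. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 3.0 and the mm10 genome. The role of each tool, and the filter that chose the deposited barcodes, are not given in the sources used here. The matrices held 52636 Ensembl gene IDs, of which 52403 had a symbol in GENCODE M21, the source of gene names and coordinates.

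Grouping followed the labels, with 1 Mlkl-null library and 1 Casp8-mutant library. The libraries held 1478 and 1014 barcodes, 2492 in all, with a UMI for 26640 and 24164 genes. Cells with fewer than 500 genes (39 and 139 barcodes) or more than 20% mitochondrially encoded UMIs (0 and 0) were left out. Median mitochondrial shares were 1.09% and 0.480%, with highest values of 13.9% and 4.55%. Of the barcodes under 500 genes, 38 and 121 had most of their UMIs from haemoglobin genes. Scrublet, run within scanpy on each library, called 5 and 2 doublets, which were removed, and such low numbers leave undetected doublets possible. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes of each library, joined and without sex-linked genes, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1 with seed 0. The libraries were clustered together without integration.

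Clusters were named from marker lists fixed before the data were examined. A marker counted if at least 25% of the cells of some cluster held a UMI of it. Classes were ordered by the number of such markers at 50% or more of the highest cluster mean, and the best class with at least 3 markers among the 50 leading genes was taken, with 5 per 10000 added to the means compared. A name was kept if 3 markers were found in at least 10% of cells and the 10 leading genes held no more markers of another class. Erythroid names also needed a median haemoglobin share of at least 20%. This rule was revised several times after the clusters, and the shares it gave under other settings, had been seen. The revisions were made because the earlier forms left many epithelial-like cells unnamed, or named cells carrying free haemoglobin transcripts as erythroid. The form written earliest was kept as an alternative, and names are written as "-like". A cluster of enteroendocrine and islet markers was kept out of the epithelial class after its leading genes were seen.

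Within each class the UMIs of a gene were summed per library and divided by the class total. The ratio of Casp8-mutant over Mlkl-null used 0.5 UMI added to each sum. Intervals for levels are exact Poisson intervals, those for ratios conditional exact intervals and those for shares Clopper-Pearson intervals, all at 95%. With 1 sample per group no test, p-value or count of significant genes was computed. Cells were not treated as replicates. At the depths found, intervals on a ratio are wide for genes with few UMIs, so a gene against 0 is given only as at least a fold, with a floor of 3 counts. Such a fold sets the 0 at 3 counts, and the lower limit of the ratio interval can lie below it. Classes with at least 100 cells in each library were to be compared, which the epithelial class alone met. Classes with 50 to 99 cells, fibroblast-like and myeloid-like, were added after the cell numbers were seen.

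Named genes followed a rule written before the data were examined. Candidates had at least 50 UMIs over both libraries and 50 counts per 1 M UMIs in either. Mitochondrial, ribosomal, haemoglobin, sex-linked and predicted genes were excluded, as were genes below 25% of their level in another class of at least 50 cells. They were ranked by the interval bound nearest to 1, and 12 higher and 12 lower genes were named in epithelial-like and fibroblast-like cells and 5 of each in myeloid-like cells and over all cells. Casp8, Mlkl, Ripk1, Ripk3, Casp1, Pycard, Gsdmd, Casp4, Zbp1, sex-linked and haemoglobin genes were always looked up. Gene lists written before the data were examined covered cell death, inflammasome, interferon-stimulated, NF-kB and TNF target, MHC class I, MHC class II, p53 target, endoplasmic reticulum stress, hypoxia and glycolysis, immediate-early, proliferation, intestinal stem, fetal or regenerative, lipid transport, brush border, goblet, enteroendocrine, antimicrobial, junction, fibrillar matrix, villus mesenchyme, smooth muscle, mitochondrially encoded, haemoglobin and sex-linked genes. Of the 17 fetal or regenerative symbols, 14 were matched. A member was measured with at least 20 UMIs, and the examples given are the highest-level and farthest-ratio members, with a selection of them in smaller classes. A member was higher or lower by size at 1.5-fold or more with an interval that left out 1. Each list median was ranked among 10000 random lists matched in 20 expression bins, which is a description and not a test. Shares of cells with list transcripts used 3 or more UMIs after thinning each cell to 2000 UMIs. Genes with near-identical copies, such as Hba-a1 and Hba-a2, defensins and MHC heavy chains, may share or lose reads, and how these were assigned is not given in the sources used here.

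The ratio intervals and the size rule were tested on simulated Poisson counts, with 200 genes per comparison altered. Counts for both libraries were drawn from the mean of their real gene proportions. These draws held counting error alone, so they do not show error from spread between cells or embryos. In epithelial-like cells 96.3% of intervals held the set ratio over 14038 genes, 96% of 2-fold higher and 86% of 2-fold lower genes were recovered, and 2.11% of unaltered genes were called. The same values were 96.6%, 86%, 84% and 3.26% in fibroblast-like cells. They were 96.8%, 84%, 90% and 3.27% in myeloid-like cells. Over all cells they were 96.1%, 90%, 80% and 1.98%. Genes altered 4-fold were all recovered. The alternatives tried were other cell filters, kept doublets, other cluster resolutions, separate clustering, thinning, other scalings, per-cell weighting, other member minimums and thresholds. Some were added after seeing the data, namely re-clustered epithelial groups of equal weight, other limits of the epithelial and myeloid classes, members left out by chromosome or by level in other classes, and the earliest naming form. The 6 epithelial groups came from a separate clustering on 672 genes variable in both libraries. It used 20 principal components and resolution 0.5, and the pairing of the libraries within groups depends on this step. A value that would read the same as a round setting in the scripts was given 1 more digit. Trimmed-mean scaling factors came from edgeR 4.0.16 in R 4.3.3, which was used for nothing else. The other steps used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Classes too small to compare, intercellular signalling, trajectories, splicing and the correction of free RNA were not analysed here. Results for 2 single genes are not reported here.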

Results

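The data were single-cell RNA libraries from the intestines of 2 mouse embryos at stage E18.5, both on the C57BL/6 background. The reference embryo lacked Mlkl, which encodes the pore-forming executor of necroptosis, and is called the Mlkl-null embryo. The other embryo lacked Mlkl and was homozygous for Casp8 C362A, an allele that replaces the catalytic cysteine of caspase-8, and is called the Casp8-mutant embryo. The comparison asked how intestinal cells with catalytically inactive caspase-8 differ from cells with active caspase-8 when Mlkl is absent from both. There was 1 embryo per genotype, so no test was made and no difference has a replicate check. Every interval is a 95% interval that covers counting error only. The Mlkl-null library held 1478 barcodes and 6290008 unique molecular identifiers (UMIs), with a median of 3654 UMIs per barcode (range 1247 to 30885). The Casp8-mutant library held 1014 barcodes and 2804929 UMIs, with a median of 1797.5 UMIs per barcode (range 974 to 18448). After filtering, 1434 and 873 cells were retained, with medians of 3710.5 and 1957 UMIs and of 1810.5 and 1060 detected genes.

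Casp8 was detected in both libraries, Mlkl was near the detection limit in both, and sex-linked genes differed between the embryos. Of each pair of values the Mlkl-null one comes first, and levels are in counts per 1 M UMIs (CPM). Casp8 (ENSMUSG00000026029, chromosome 1, 58795374 to 58847503, mm10) had 399 and 233 UMIs, or 64.7 and 89.6 CPM, a ratio of 1.39 (1.17 to 1.63). Mlkl (ENSMUSG00000012519, chromosome 8, 111311797 to 111338177) had 1 and 13 UMIs, a ratio of 21.4 (4.63 to 1311). Tags from transcript 3' ends neither read the Casp8 substitution nor necessarily fall within the deleted part of Mlkl, so these counts do not check the genotypes. Xist, the noncoding RNA that silences an X chromosome in female cells, had 2 and 8256 UMIs. Its antisense partner Tsix had 2 and 681 UMIs, and how reads were assigned by strand is not given in the sources used here. The Y-linked genes Ddx3y (275 and 2 UMIs), Eif2s3y (113 and 0), Kdm5d (108 and 0) and Uty (88 and 1) went the opposite way, so of the 6 sex-linked genes 2 were higher and 4 lower. The Mlkl-null embryo thus had a male expression pattern and the Casp8-mutant embryo a female pattern, and sex cannot be separated from genotype in any comparison.

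Among other regulators of cell death, Zbp1, Ripk3, Casp4 and Casp1 were higher over all cells of the Casp8-mutant library. Zbp1 (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923), an interferon-inducible sensor of nucleic acids, was at 6.32 and 157 CPM, 24.5-fold higher (17.8 to 35.4). Ripk3, the kinase that phosphorylates MLKL, was at 22.4 and 53.5 CPM, 2.39-fold higher (1.87 to 3.05). Casp4, the murine caspase-11 gene, was 2.42-fold higher (1.90 to 3.09), and Casp1, whose product matures interleukin-1, 1.501-fold higher (1.06 to 2.10). Ripk1 (28.5 and 24.6 CPM), the pyroptosis pore gene Gsdmd (93.7 and 98.1 CPM) and the inflammasome adaptor gene Pycard (713 and 642 CPM) differed by less than the 1.5-fold size rule. Over all cells, the cell death list had 3 of 16 genes higher, 2 lower (Fadd and Casp9, named after their values were seen) and 11 neither, with a median of 0.04 (-0.15 to 0.24). The inflammasome list had 6 of 17 higher, 5 lower and 6 neither, with a median of 0.20 (0.00 to 0.34). The log2 ratio of Pycard, -0.15, moved to 0.02 when libraries were scaled by the median of ratios. Transcripts of the adult beta-globin genes were also higher, with Hbb-bs at 5295 and 9729 CPM and Hbb-bt at 1327 and 2349.6 CPM. The alpha-globin genes Hba-a1 (1129 and 1513 CPM) and Hba-a2 (759 and 850.1 CPM) and the embryonic Hba-x (489 and 536 CPM) lay within the size rule, and the embryonic Hbb-y (16 and 4 UMIs) and Hbb-bh1 (32 and 21 UMIs) were rare.

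The cell types recovered differed between the libraries, with more myeloid-like and granulocyte-like cells and fewer enteric neuron-like cells in the Casp8-mutant library. Epithelial-like cells were 1169 and 590 cells, or 81.5% (79.4 to 83.5) and 67.6% (64.4 to 70.7). Myeloid-like cells were 61 and 109 cells, or 4.25% (3.27 to 5.43) and 12.5% (10.4 to 14.9), a ratio of 2.92 (2.13 to 4.08). A granulocyte-like cluster with S100a9, S100a8 and Stfa1 among its leading genes held 1 and 21 cells, or 0.0697% (0.00177 to 0.388) and 2.41% (1.495 to 3.65). Since it was almost wholly made of cells from the Casp8-mutant library, it may mark that library as well as a cell type. Fibroblast-like cells were 3.84% (2.90 to 4.96) and 6.53% (4.98 to 8.38). Enteric neuron-like cells, which carried the axonal genes Stmn2 and Prph, were 49 and 10 cells, or 3.42% (2.54 to 4.49) and 1.15% (0.551 to 2.10), a ratio of 0.348 (0.151 to 0.670). Their summed neuron markers were at 5462 and 9648 CPM. Epithelial markers, a list that includes hormone genes, were at 18535 and 56153 CPM, against 44535 CPM in Casp8-mutant epithelial-like cells. The identity of the 10 Casp8-mutant cells is therefore less sure. A cluster that mixed enteroendocrine and pancreatic islet markers, led by Sct, Ghrl and Pyy, was kept out of the epithelial class after its leading genes were seen and held 3.07% and 3.89%. Erythroid-like (1.39% and 2.63%), lymphoid-like (0.907% and 1.60%), pancreatic acinar-like (0.907% and 0.802%) and smooth muscle-like cells (0.628% and 0.115%) were small classes. Before filtering, barcodes with most of their UMIs from haemoglobin genes were 3.52% (2.64 to 4.59) and 12.1% (10.2 to 14.3) of all barcodes.

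**Figure D1:**
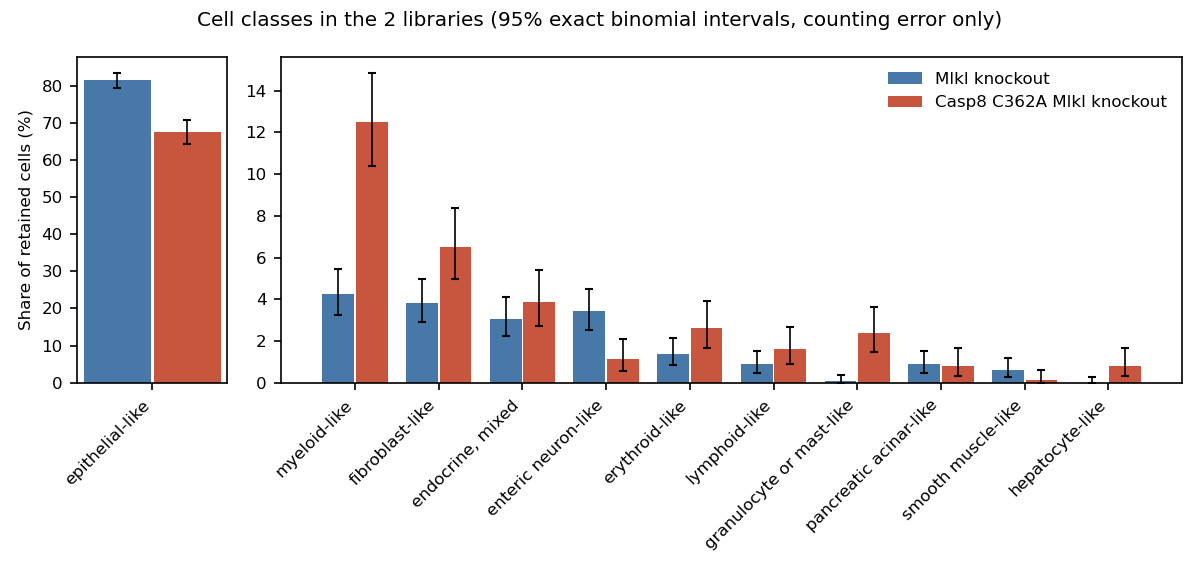
Share of retained cells in each named class (percent, vertical axis) in the Mlkl-null and Casp8-mutant libraries, 1 embryo each, with bars for shares, lines for exact 95% binomial intervals and a separate scale for epithelial-like cells. Myeloid-like cells were 4.25% and 12.5% and enteric neuron-like cells 3.42% and 1.15%.

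Among cells outside both the epithelial class and the mixed endocrine cluster, myeloid-like and granulocyte-like shares stayed higher and the enteric neuron-like share lower in the Casp8-mutant library. Myeloid-like cells were 27.6% of 221 and 43.8% of 249 such cells, and granulocyte-like cells 0.452% and 8.43%. Enteric neuron-like cells were 22.2% (16.9 to 28.2) and 4.02% (1.94 to 7.26), and fibroblast-like cells 24.9% and 22.9%. Erythroid-like cells were 9.05% and 9.24% and lymphoid-like cells 5.88% and 5.62%. The erythroid-like share depended on the cell filter. With no filter, erythroid-like cells were 57 and 142 cells, or 3.87% and 14.0% of all cells of each library.

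Class shares depended on the cell filter, the clustering and the naming rule. The epithelial share was 84.2% and 81.9% under the stricter filter and 86.9% and 84.7% after cells were thinned to 2000 UMIs. With the earliest form of the naming rule, an alternative chosen after the data were seen, it was 83.9% and 49.9% under the stricter filter and 60.8% and 59.7% with no filter. With that form the order was the opposite with doublets kept (62.6% and 65.3%), at resolution 0.5 (63.0% and 70.6%) and after thinning (75.2% and 84.7%). The enteric neuron share was 1.60% and 1.15% at resolution 2 and 3.28% and 0% with each library clustered alone. The lymphoid share was 0.907% and 3.44% at resolution 2 and 0.907% and 3.55% with each library clustered alone. No lymphoid-like class formed with doublets kept or after thinning. The fibroblast share was 0.708% and 3.71% under the stricter filter, 0.625% and 3.09% with doublets kept and 0% and 6.64% with each library clustered alone. With doublets kept, granulocyte-like cells were 15 and 53 cells, or 1.04% and 6.06%. They formed no cluster of their own under the stricter filter, at the lower resolution, after thinning or with each library clustered alone.

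Epithelial-like cells of the Casp8-mutant library had far more transcripts of antimicrobial and interferon-induced genes, and far fewer transcripts of genes for fatty acid handling and digestion. Reg3g, Reg3b, Ly6a and Isg15 were among the genes that were higher, and Fabp1, Mme, Leap2 and Lct among those that were lower. Nearly all Mlkl-null cells of this class lay in clusters 1, 2, 4, 6, 7, 11 and 14 and most Casp8-mutant ones in clusters 18, 19 and 21, and only cluster 9 held both (6 and 85 cells). Small nuclear RNA genes, Reg3b and Isg15 were among the leading genes of cluster 18, and Reg3b, Reg3g and Ly6a among those of cluster 19. Rn7sk, Gm23935 and Gm26917 were leading genes of cluster 18 and also of cluster 4, which held 144 Mlkl-null cells. Median depths of the class were 3896 and 2473 UMIs. Reg3g (ENSMUSG00000030017, chromosome 6, 78466269 to 78468872), a secreted lectin that binds bacterial peptidoglycan, had 16 and 4367 UMIs (3.07 and 2165 CPM), 684-fold higher (434 to 1235). Its neighbour Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466), a related bactericidal lectin gene, was at 39.3 and 4808 CPM, 122-fold higher (106 to 141). Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), which encodes the surface protein Sca-1, had 6 and 1909 UMIs, 759-fold higher (377 to 2243). Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein gene induced by interferon, was at 16.5 and 1748 CPM, 105-fold higher (85.5 to 133).

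The other higher genes named by the rule encode proteins of several kinds. Ubd (ENSMUSG00000035186, chromosome 17, 37193892 to 37196095), which encodes the ubiquitin-like modifier FAT10, had 0 and 202 UMIs, at least 174-fold higher against a floor of 3 counts. The GTPase gene Iigp1 had 0 and 127 UMIs, at least 109-fold higher, and Oas2, a sensor of double-stranded RNA, 1 and 204 UMIs, a ratio of 352 (93.6 to 20921). Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, had 3 and 311 UMIs, a ratio of 230.0 (90.8 to 1306), and Slfn4, a myeloid growth regulator, 5 and 393 UMIs. S100a9 (6.14 and 1411 CPM), S100a8 (9.59 and 1485 CPM) and Stfa2 (1 and 197 UMIs) also met the rule, but in the Casp8-mutant library they stood at 6.38%, 9.99% and 4.78% of their levels in granulocyte-like cells.

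**Figure D2:**
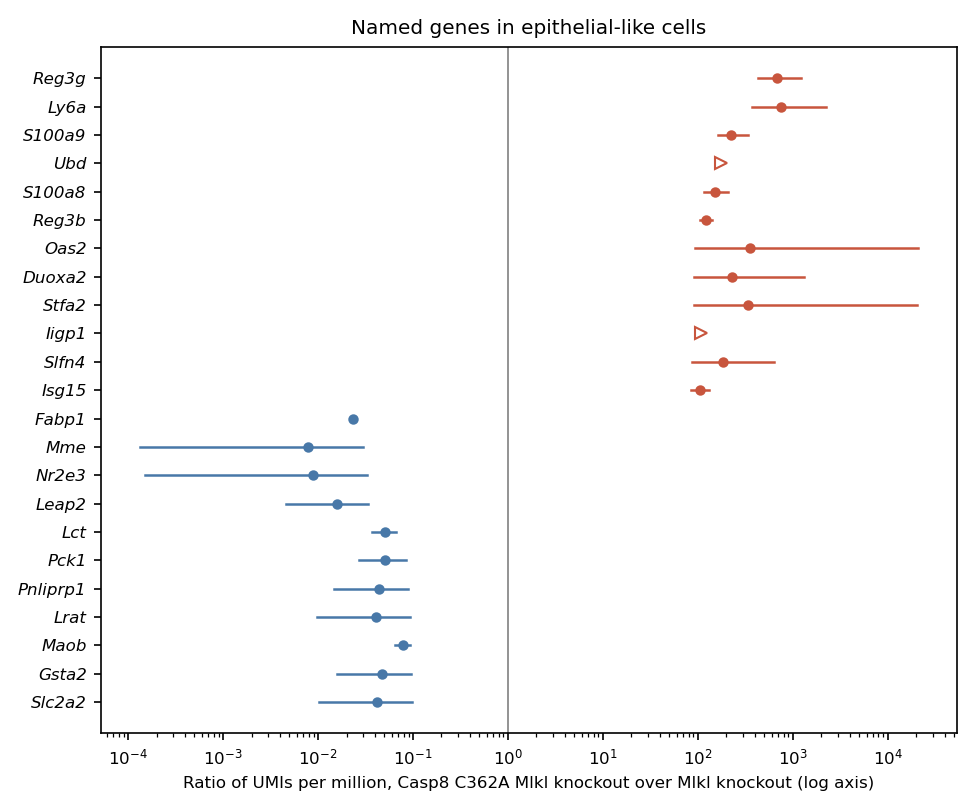
Ratio of CPM (Casp8-mutant over Mlkl-null, log axis) of named genes in epithelial-like cells, 1 embryo per genotype, with lines for 95% counting intervals and open triangles for the least ratio of genes without an upper limit. Reg3g stood at 684 and Fabp1 at 0.0234.

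Enterocyte genes led those that were lower in Casp8-mutant epithelial-like cells. Fabp1 (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023), the liver-type fatty acid-binding protein gene of enterocytes, had 73899 and 668 UMIs (14179 and 331 CPM), 42.8-fold lower (39.7 to 46.3). Mme (ENSMUSG00000027820, chromosome 3, 63241537 to 63386030), which encodes the peptidase neprilysin, had 487 and 1 UMIs, 126-fold lower (33.7 to 7459), and the nuclear receptor gene Nr2e3 437 and 1 UMIs, 113-fold lower (30.2 to 6695). Leap2 (ENSMUSG00000036216, chromosome 11, 53422181 to 53423170), an antimicrobial peptide gene whose product also blocks the ghrelin receptor, had 905 and 5 UMIs, 63.7-fold lower (29.9 to 216). Lct (ENSMUSG00000026354, chromosome 1, 128284756 to 128328318), the lactase gene, was at 493 and 24.8 CPM, 19.7-fold lower (15.04 to 26.9). Pck1, a gluconeogenic enzyme gene, was 19.4-fold lower (11.9 to 37.0) and the X-linked amine oxidase gene Maob 12.7-fold lower (10.6 to 15.4). Lrat, which esterifies retinol, had 286 and 4 UMIs, the glutathione transferase gene Gsta2 358 and 6 UMIs and the glucose transporter gene Slc2a2 274 and 4 UMIs. Pnliprp1 (384 and 6 UMIs) also met the rule, but it is a lipase gene of pancreatic acinar cells and was far higher in acinar-like than in epithelial-like cells.

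Interferon-stimulated and MHC class I genes were higher without exception in Casp8-mutant epithelial-like cells. All 32 interferon-stimulated genes were higher by size (at least 1.5-fold, with an interval that left out 1), with a median log2 ratio of 5.17 (4.79 to 5.27), above all 10000 random lists matched on expression. Ifitm3, which restricts viral entry, was at 25.5 and 993 CPM, 38.8-fold higher (32.6 to 46.7), beside Isg15 and Iigp1. In 6 epithelial groups re-clustered after the data were seen, E0 to E5, the interferon list median lay between 4.03 in E3 and 6.15 in E4. Some groups paired different clusters by library, as E3 with 85 Mlkl-null cells of cluster 6 and 157 Casp8-mutant cells of cluster 19. E2 likewise paired 123 cells of cluster 4 with 120 of cluster 18. Casp8-mutant cells were few in E1, mainly 20 of cluster 19, 7 of cluster 21 and 3 of cluster 18, against 126 Mlkl-null cells of cluster 2. In E5 they were 18 of cluster 18 and 9 of cluster 21, against Mlkl-null cells that included 161 of cluster 11 and 132 of cluster 14. Group medians may therefore carry a different mix of cells, and those of E1 and E5 rest on few Casp8-mutant cells. After each cell was thinned to 2000 UMIs, 95 of 1039 Mlkl-null cells, or 9.14% (7.46 to 11.1), and 343 of 350 Casp8-mutant cells, or 98% (95.9 to 99.2), carried 3 or more UMIs of the list. Thinning left out 130 and 240 cells of lower depth, and without it the shares were 28.6% and 99.8%. All 14 measured genes of MHC class I presentation were higher, with a median of 1.99 (1.79 to 2.07). B2m, the light chain of class I molecules, was at 304 and 1451 CPM, 4.76-fold higher (4.48 to 5.07), and the heavy chain gene H2-D1 was 3.34-fold higher (3.11 to 3.58). The peptide transporter gene Tap1 was 13.8-fold higher (10.1 to 19.7) and the immunoproteasome gene Psmb8 13.2-fold higher (10.8 to 16.3).

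**Figure D3:**
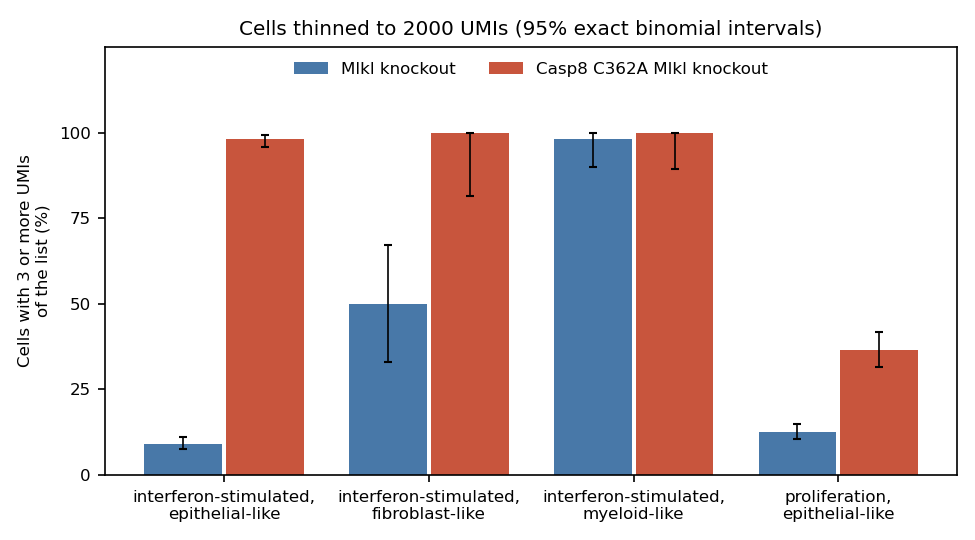
Percent of cells with 3 or more UMIs of the interferon-stimulated list in 3 classes and of the proliferation list in epithelial-like cells (vertical axis), each cell thinned to 2000 UMIs, by library, 1 embryo each, with lines for exact 95% binomial intervals. The epithelial-like interferon shares were 9.14% and 98%, and the myeloid-like ones 98.1% and 100%.

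Antimicrobial and NF-kB target genes were mostly higher, while the cell death and inflammasome lists were centred near 0 over all epithelial-like cells together. Of 20 antimicrobial genes, 16 were higher, 0 lower and 4 neither, with a median of 5.64 (5.14 to 6.40), or 4.80 with members at 0 in 1 library set at their bound. Beside Reg3b, Reg3g and S100a9, its examples held the defensin gene Defa24, at 1453 and 1552 CPM. Of 18 targets of NF-kB and TNF signalling, 14 were higher and 0 lower, with a median of 1.73 (1.37 to 1.93). Nfkbia, the feedback inhibitor of NF-kB, was 2.49-fold higher (2.23 to 2.77), while Cxcl2 (5.76 and 459 CPM) and Tnfaip2 (1.34 and 25.8 CPM) stood at 8.76% and 6.31% of their granulocyte-like levels. In the cell death list, Zbp1 (59.2-fold, 35.4 to 117), Ripk3 (2.50-fold, 1.93 to 3.24) and the death receptor gene Fas, named after its value was seen, were higher and 13 of 16 members were neither, with a median of -0.00 (-0.17 to 0.31). By group the cell death median was 0.36 in E0, 0.52 in E1, 0.54 in E2, -0.40 in E3, 0.79 (0.49 to 1.21) in E4 and 1.14 (0.19 to 1.63) in E5. As given above, E1 and E5 held few Casp8-mutant cells. Casp8 itself was at 71.6 and 102 CPM. A Zbp1 UMI was found in 1.11% and 33.4% of epithelial-like cells at their full, unequal depth. In the Casp8-mutant library the share was 31.6% in fibroblast-like (18 of 57) and 30% in enteric neuron-like cells (3 of 10). It was 28.6% in lymphoid-like (4 of 14), 23.8% in granulocyte-like (5 of 21), 8.82% in mixed endocrine (3 of 34) and 4.35% in erythroid-like cells (1 of 23). Mlkl-null shares were 1.82% in fibroblast-like (1 of 55) and 0% in enteric neuron-like, lymphoid-like, mixed endocrine and erythroid-like cells. In myeloid-like cells the shares were 27.9% and 28.4%. The cells were too few to rank the small classes. The inflammasome list split into 6 higher, 5 lower and 5 neither, with a median of -0.01 (-0.14 to 0.11), and by group 0.14 in E0, 1.03 (0.20 to 1.39) in E1, 0.22 in E2, -1.06 (-1.63 to -0.70) in E3, 0.27 in E4 and -0.22 in E5. Casp4 was 2.61-fold higher (2.01 to 3.37), Casp1 1.67-fold higher (1.16 to 2.37), and Pycard (773 and 734 CPM) and Gsdmd (99.6 and 113 CPM) were neither, while the genes for sensors of bacterial proteins Naip1, Naip5 and Naip6, named after their values were seen, were among the lower members. Il1b (4.03 and 158 CPM) and Il1rn (0.576 and 69.9 CPM) stood at 11.4% and 8.74% of their granulocyte-like levels.

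Genes of lipid transport and of the brush border were lower in Casp8-mutant epithelial-like cells. Of 18 lipid transport genes, 17 were lower and 0 higher, and only the lipoprotein receptor gene Scarb1, named after its value was seen, was neither, with a median of -1.91 (-2.02 to -1.84), below all 10000 matched random lists, and by group -1.45 in E0, -1.11 in E1, -2.28 in E2, -2.92 in E3, -0.42 in E4 and -0.53 in E5. Beside Fabp1, the apolipoprotein gene Apoa1 was at 9179.5 and 5237 CPM, a ratio of 0.571 (0.559 to 0.583), and the fatty acid translocase gene Cd36 at 172 and 12.4 CPM, a ratio of 0.0736 (0.0465 to 0.107). Of 20 brush border and nutrient transport genes, 14 were lower, 0 higher and 6 neither, with a median of -1.33 (-1.45 to -1.22), and by group -1.21 in E0, 0.64 in E1, -1.499 in E2, -2.39 in E3, -0.01 in E4 and 0.00 in E5. Lct and Slc2a2 were far lower, while the microvillar protein gene Cdhr5 was at 823 and 616 CPM and the aminopeptidase gene Anpep at 636 and 699 CPM.

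Goblet and enteroendocrine genes were higher over all Casp8-mutant epithelial-like cells together. Of 14 goblet cell genes, 11 were higher, 1 lower and 2 neither, with a median of 1.06 (0.92 to 1.22). In E0, the group with Muc2 and Tff3 among its leading genes, the median was 0.37, with 6 genes higher and 3 lower. E0 held 7.10% and 16.1% of epithelial-like cells. The goblet median was larger in the groups not led by goblet genes, at 2.54 in E1, 2.66 in E2, 1.70 in E3, 2.87 in E4 and 2.57 in E5. The list was also higher in myeloid-like cells, with a median of 1.17, though it was near 0 in fibroblast-like cells (0.13). Free RNA of goblet cells was not separated from expression in these groups. The gel-forming mucin gene Muc2 was at 124 and 579 CPM, 4.66-fold higher (4.23 to 5.14), the trefoil factor gene Tff3 at 4953 and 18139 CPM, 3.66-fold higher (3.604 to 3.72), and the bacteria-binding lectin gene Zg16 at 15.7 and 1379 CPM, 87.1-fold higher (70.4 to 111). Spink4, a protease inhibitor gene, was 1.85-fold higher (1.80 to 1.91). Of 12 enteroendocrine genes, 9 were higher, 0 lower and 3 neither, with a median of 1.78 (1.64 to 1.90), and by group -0.14 in E0, 0.40 in E1, 2.13 in E2, 1.15 in E3, 1.66 in E4 and 1.57 in E5. The hormone genes Sct (493 and 1596 CPM), Sst (7.67 and 55.0 CPM) and Tac1 (4.80 and 43.1 CPM) were higher and Ghrl (255 and 296 CPM) was neither. In Casp8-mutant epithelial-like cells they stood at 2.93%, 0.597%, 4.95% and 0.937% of their levels in the mixed endocrine cluster.

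**Figure D4:**
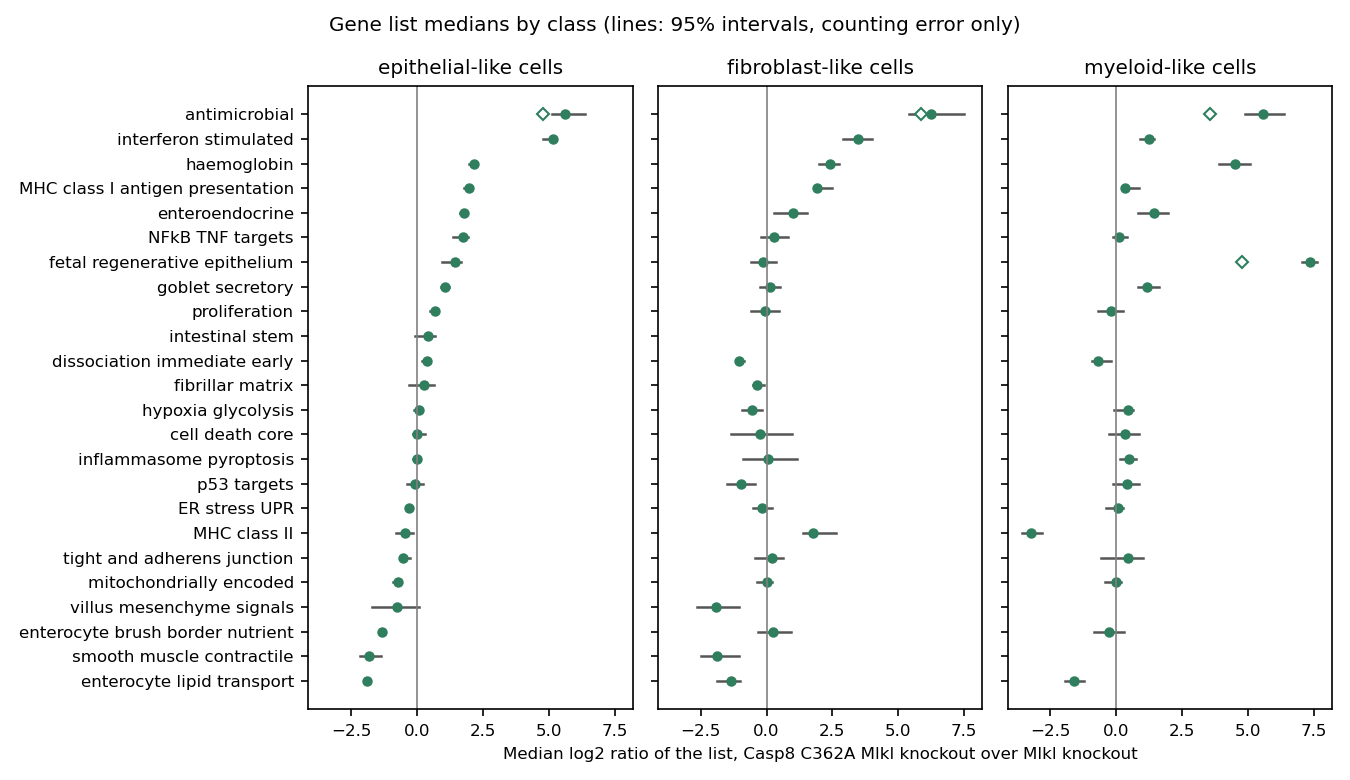
Median log2 ratio (Casp8-mutant over Mlkl-null, horizontal axis) of each gene list in epithelial-like, fibroblast-like and myeloid-like cells, with lines for 95% counting intervals and open diamonds for medians with members at 0 set at their bound. In epithelial-like cells the interferon-stimulated list stood at 5.17 and the lipid transport list at -1.91.

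Proliferation genes were higher over all Casp8-mutant epithelial-like cells together, but not in every group of them. Of 26 genes, 14 were higher, 1 lower and 11 neither, with a median of 0.70 (0.49 to 0.78), at percentile 99.95 of matched random lists. The ribonucleotide reductase gene Rrm2 was 3.09-fold higher (2.36 to 4.07), the mitotic kinase gene Plk1 2.85-fold higher (1.96 to 4.16), the chromatin protein gene Hmgb2 1.75-fold higher (1.56 to 1.96) and the ubiquitin-conjugating enzyme gene Ube2c 1.59-fold higher (1.38 to 1.83). In the 6 groups the list median was 2.46 in E3, 1.32 in E2, -0.15 in E4, -0.20 in E5, -0.89 in E0 and -2.53 in E1, the group with Ccnb2 and Mki67 among its leading genes. E3 set 157 Casp8-mutant cells of cluster 19 against 85 Mlkl-null cells of cluster 6. The Mlkl-null cluster 2, which shared the leading genes Edn1, Lgals4 and Krt8 with cluster 19, had 126 cells in E1, beside 20 of cluster 19. The medians of E1 and E3 may therefore not compare like cells. Summed over the list the level was 854 and 1319 CPM. After thinning, 131 cells, or 12.6% (10.6 to 14.8), and 128 cells, or 36.6% (31.5 to 41.9), carried 3 or more UMIs of the list, and another random thinning gave 13.1% and 40.6%. Other classes rested on few cells. Fibroblast-like cells gave 27.8% (10 of 36, 14.2 to 45.2) and 38.9% (7 of 18, 17.3 to 64.3). Enteric neuron-like cells gave 47.6% (10 of 21, 25.7 to 70.2) and 33.3% (1 of 3, 0.840 to 90.6). The mixed endocrine cluster gave 10.3% (2.87 to 24.2) and 22.2% (2.81 to 60.0). Myeloid-like cells gave 18.9% and 48.5% although the list there was at 1216 and 962 CPM. With free RNA of unknown amount in each library, no share of cycling cells was read from these values.

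Stem cell genes were mixed and fetal or regenerative genes higher in Casp8-mutant epithelial-like cells. Of 12 intestinal stem cell genes, 4 were higher, 2 lower and 6 neither, with a median of 0.40 (-0.07 to 0.68), and -0.92 in E0, -1.998 in E1 and 1.93 in E3, the groups with at least 3 measured members. As with proliferation genes, E1 and E3 may not compare like cells. The Wnt target gene Axin2 was 3.32-fold higher (2.14 to 5.23) and the transcription factor gene Sox9 1.62-fold higher (1.32 to 1.99), while the ion cotransporter gene Slc12a2 was 2.16-fold lower (1.61 to 3.01). Of 9 fetal or regenerative genes, 5 were higher, 1 lower and 3 neither, with a median of 1.46 (0.94 to 1.68), and by group 1.95 in E0, 0.996 in E1, 1.33 in E2, 1.36 in E3, -0.30 in E4 and 1.13 in E5. These included Ly6a and Anxa1 (7.07-fold, 4.51 to 11.7), an annexin gene that stood at 15.6% of its fibroblast-like level, and the keratin gene Krt7 (194 and 158 CPM).

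Mitochondrially encoded genes and several junction genes were lower in Casp8-mutant epithelial-like cells. Of 13 mitochondrially encoded genes, 8 were lower and 5 neither, with a median of -0.73 (-0.90 to -0.64). By group the median was -0.78 in E0, 0.05 in E1, -1.18 in E2, -0.84 in E3, -0.07 in E4 and 0.12 in E5. The complex I genes mt-Nd1 (2263 and 762 CPM) and mt-Nd4 (1429.6 and 524 CPM) and the cytochrome b gene mt-Cytb (1815 and 745 CPM) were its examples. Junction genes had 3 of 17 higher, 6 lower and 8 neither, with a median of -0.51 (-0.61 to -0.26), which moved to 0.07 with the groups weighted alike and was by group -0.39 in E0, -0.01 in E1, 0.08 in E2, -0.74 in E3, 0.21 in E4 and 1.09 in E5. The claudin gene Cldn4 was 1.60-fold higher (1.48 to 1.73), Cldn7 was at 1184 and 969.7 CPM, the occludin gene Ocln 2.05-fold lower (1.62 to 2.64) and Cldn1 3.42-fold lower (1.59 to 10.4). Hypoxia and glycolysis genes split into 4 higher, 5 lower and 10 neither, with a median of 0.08 (-0.11 to 0.17). The stress-responsive gene Ndrg1 was at 976 and 117 CPM, the mitophagy receptor gene Bnip3 at 57.4 and 25.8 CPM and the lactate dehydrogenase gene Ldha at 997 and 931 CPM. Genes of the endoplasmic reticulum stress response had 3 higher, 5 lower and 8 neither of 16, with a median of -0.30 (-0.43 to -0.21). Its chaperone genes Calr (1423 and 1158 CPM) and Hsp90b1 (400.0 and 233 CPM) and the co-chaperone gene Dnajb9 (182 and 66.4 CPM) stood beside the rare Chac1 (8 and 15 UMIs).

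The p53 target list had 4 of 15 genes higher, 3 lower and 8 neither in epithelial-like cells, with a median of -0.08 (-0.37 to 0.24). The cell cycle inhibitor gene Cdkn1a was 1.71-fold higher (1.52 to 1.93), the apoptosis effector gene Bax was at 219 and 157 CPM, Trp53inp1 was 2.94-fold lower (1.79 to 5.45) and Aen 4.38-fold higher (2.02 to 10.4). Immediate-early genes, which respond to tissue dissociation, had 7 of 18 higher, 2 lower and 9 neither, with a median of 0.37 (0.19 to 0.48). The heat shock genes Hspa1a and Hspa1b were 5.19-fold higher (3.73 to 7.37) and 5.77-fold higher (3.88 to 8.87), while the transcription factor genes Jun (861 and 478 CPM) and Klf6 (800.1 and 477 CPM) were lower. The 5 measured haemoglobin genes were all higher, with a median of 2.15 (1.99 to 2.21), and Hbb-bs was at 2325 and 8061 CPM, or 6.98% of its erythroid-like level in the Casp8-mutant library. Smooth muscle contractile genes were lower in 11 of 12 with a median of -1.80 (-2.16 to -1.37), and included the myosin kinase gene Mylk (209.9 and 79.3 CPM) and the tropomyosin genes Tpm1 (356 and 387 CPM) and Tpm2 (24.0 and 4.96 CPM). Tpm2 stood at 9.71% of its fibroblast-like level, and Mylk and Tpm1 at 139% and 94.8%. Smooth muscle-like cells, 9 in the Mlkl-null library, were too few to serve as that reference. Their summed smooth muscle markers were at 104631 CPM, against 343 CPM in Mlkl-null epithelial-like cells. Free RNA from them was not separated from expression. MHC class II genes had a median of -0.47 (-0.81 to -0.15) over 5 genes, and Cd74, H2-Ab1 and H2-Eb1 stood at 0.475%, 1.02% and 0.805% of their myeloid-like levels in the library where they were higher. Fibrillar matrix genes had a median of 0.25 (-0.30 to 0.65) over 9 genes, and Col1a1 and Sparc stood at 0.600% and 0.747% of their fibroblast-like levels. Of the villus mesenchyme signal genes, 4 were measured, with the bone morphogenetic protein genes Bmp2 1.89-fold higher (1.39 to 2.56) and Bmp7 4.45-fold lower (3.19 to 6.57) and a median of -0.76 (-1.70 to 0.06).

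Fibroblast-like cells of the Casp8-mutant library were also higher in interferon-stimulated and MHC class I genes. They were lower in contractile, villus signalling and immediate-early genes. The comparison asked whether the epithelial differences were shared by the stroma, and its 55 and 57 cells, with median depths of 2411 and 1551 UMIs, were fewer than the 100 per library set before the data were examined. The class was therefore added after cell numbers were seen. Of 14 interferon-stimulated genes, 13 were higher and 1 neither, with a median of 3.46 (2.91 to 4.01). The mitochondrial protein gene Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) was at 172 and 3968 CPM, 22.9-fold higher (16.9 to 32.6), Isg15 15.3-fold higher (9.29 to 28.9), and the interferon regulatory factor gene Irf7 had 1 and 39 UMIs, a ratio of 40.0 (10.0 to 2400.2). Ifitm3 was 4.85-fold higher (4.15 to 5.71) and the virus tether gene Bst2 7.86-fold higher (5.51 to 11.8). All 9 measured MHC class I genes were higher, with a median of 1.93 (1.79 to 2.49), including B2m (5.36-fold, 4.18 to 7.005) and Psmb8 (17.1-fold, 6.97 to 72.4). All 4 MHC class II genes were higher, with a median of 1.77 (1.37 to 2.65), including Cd74 (159 and 432 CPM) and H2-Eb1 (5 and 33 UMIs).

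The acute phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) led the genes that were higher in fibroblast-like cells, with 0 and 133 UMIs, at least 67.4-fold higher, and Ly6a was 20.7-fold higher (11.1 to 48.7). The secreted protease inhibitor gene Slpi was 6.53-fold higher (5.19 to 8.37), Dmkn, which is also expressed by mesothelium, 8.11-fold higher (5.78 to 11.9), Slurp1 9.19-fold higher (4.88 to 20.9) and the metalloprotease inhibitor gene Timp1 7.60-fold higher (4.19 to 16.0). S100a9 (1 and 191 UMIs) and S100a8 (4 and 221 UMIs) stood at 5.49% and 9.45% of their granulocyte-like levels. Adamdec1 (ENSMUSG00000022057, chromosome 14, 68563380 to 68582095), a metalloprotease gene of lamina propria stroma, led the lower genes with 161 and 0 UMIs, at least 35.3-fold lower. The matrix gene Mfap4 (59 and 3 UMIs) was 11.2-fold lower (4.22 to 64.5), the smooth muscle actin gene Acta2 (77 and 5 UMIs) 9.27-fold lower (4.16 to 32.1), the myosin light chain gene Myl9 4.68-fold lower (2.35 to 11.95) and the basement membrane collagen gene Col4a1 4.93-fold lower (3.08 to 8.76). The lipid-binding Fabp4 (101 and 12 UMIs), the trypsin inhibitor gene Spink1 (391 and 41), the triglyceride synthesis gene Dgat2 (206 and 34), the imprinted gene Mest (159 and 27) and Ubxn1 (61 and 7) were lower too. Ctrb1 (72 and 3 UMIs) and Stmn2 (56 and 7 UMIs) met the rule at 0.260% of the acinar-like and 14.9% of the enteric neuron-like level in the Mlkl-null library.

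Contractile genes were lower in 8 of 9 in fibroblast-like cells with a median of -1.90 (-2.48 to -1.07), and villus mesenchyme signal genes in 3 of 5 with a median of -1.94 (-2.64 to -1.07). Summed markers of other cell types in this class were at 1515 and 489.6 CPM for smooth muscle, 565 and 216 CPM for pericytes, 1569 and 382 CPM for blood endothelium and 151 and 293 CPM for lymphatic endothelium, and fibroblast markers at 9863 and 8031 CPM. Mesothelial markers were at 1101 and 1176 CPM. The villus list included the villus signal gene Bmp4 (38 and 3 UMIs) and the gut mesoderm factor gene Foxf1 (49 and 8 UMIs). Immediate-early genes were lower in 15 of 17, with a median of -1.04 (-1.17 to -0.86), including Fos (2356 and 1176 CPM) and Jun (2038 and 731 CPM). Fibrillar matrix genes were lower in 4 of 17 and otherwise neither, with a median of -0.35 (-0.51 to -0.10), and the collagen gene Col1a1 was at 2385 and 3472 CPM and the periostin gene Postn at 41 and 4 UMIs. Lipid transport genes were lower in 7 of 10 with a median of -1.34 (-1.88 to -0.99), and Fabp1 stood at 11.5% of its epithelial-like level in the Mlkl-null library. The 7 antimicrobial genes were all higher, with a median of 6.22 (5.403 to 7.50), or 5.86 with members at 0 set at their bound, and the 4 haemoglobin genes were all higher with a median of 2.42 (2.001 to 2.75). The antimicrobial members included S100a8 and S100a9, and Reg3b at 604 CPM in Casp8-mutant fibroblast-like against 4808 CPM in epithelial-like cells. Free RNA from other classes was not separated from expression here. NF-kB targets split into 3 higher, 2 lower and 5 neither with a median of 0.26 (-0.23 to 0.83), with the monocyte attractant gene Ccl2 3.21-fold higher (2.19 to 4.83) and the neutrophil attractant gene Cxcl1 1.51-fold lower (1.11 to 2.11). Enteroendocrine genes had a median of 0.995 and p53 targets of -0.97. The remaining lists with at least 3 measured members, sex-linked genes aside, had medians between -0.55 (hypoxia and glycolysis) and 0.26 (brush border). Scaling by the median of ratios moved the median log2 ratio of all genes by 0.18 in epithelial-like, 0.20 in fibroblast-like and 0.17 over all cells, and trimmed-mean factors moved it by 0.11 in fibroblast-like cells.

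Myeloid-like cells had lower MHC class II and higher interferon-stimulated genes in the Casp8-mutant library. The comparison asked whether resident immune cells shared the epithelial differences, and the class was likewise added after cell numbers were seen. Cluster 13, with Cd74 and H2-Ab1 among its leading genes, held 42 and 0 cells and cluster 15 held 19 and 109. Median depths were 2825 and 1548 UMIs. All 6 MHC class II genes were lower, with a median of -3.24 (-3.56 to -2.82). In cluster 15 alone, a choice made after the data were seen, that median was -1.37, and 10 of 10 named genes kept their direction and at least 1.5-fold. For the higher ones, Spp1, Arg1, Ly6a, S100a8 and S100a9, this was fixed in advance. Cluster 15 held all 109 Casp8-mutant cells, and Mlkl-null cells of the class had 0 or 1 UMIs of each. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) was at 2568 and 235 CPM, 10.8-fold lower (8.03 to 15.2), H2-Eb1 10.5-fold lower (7.14 to 16.7), H2-Aa 9.97-fold lower (6.97 to 15.1), and the invariant chain gene Cd74 was at 9569 and 1484 CPM. The gelatinase gene Mmp9 (71 and 5 UMIs) was 13.4-fold lower (6.01 to 46.6), and Ctrb1 (67 and 4 UMIs) stood at 0.313% of its acinar-like level. Interferon-stimulated genes were higher in 13 of 20, lower in 1 and neither in 6, with a median of 1.23 (0.89 to 1.45), including the chemokine gene Cxcl10 (7.68-fold, 4.03 to 18.3) and Ifitm3 (1.98-fold, 1.72 to 2.29). The phosphoprotein gene Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) had 0 and 85 UMIs, at least 27.4-fold higher, and the arginase gene Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) 0 and 75 UMIs, at least 24.2-fold higher. Ly6a had 0 and 105 UMIs, at least 33.8-fold higher, and S100a8 (0 and 330 UMIs) and S100a9 (1 and 304 UMIs) stood at 11.6% and 7.18% of their granulocyte-like levels.

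MHC class I genes in myeloid-like cells were higher in 4 of 12 and otherwise neither, with a median of 0.33 (0.20 to 0.86), led by B2m (2.05-fold, 1.78 to 2.36). Immediate-early genes were lower in 8 of 17, higher in 2 and neither in 7, with a median of -0.69 (-0.91 to -0.20), and included the heat shock gene Hspa1a (94 and 24 UMIs). The inflammasome list had 3 of 7 higher, 2 lower and 2 neither, with a median of 0.49 (0.15 to 0.76). Il1rn, the interleukin-1 receptor antagonist gene, was 8.13-fold higher (4.13 to 20.6) and the sensor gene Nlrp3 4.76-fold lower (2.19 to 13.4). The lysozyme gene Lyz2 was at 1984 and 706 CPM. The antimicrobial median was 5.56 over 8 genes, or 3.54 with members at 0 set at their bound, and the fetal or regenerative median was 7.37 over 3, or 4.78 at the bound. Among the antimicrobial members, Reg3b was at 664 CPM in Casp8-mutant myeloid-like against 4808 CPM in epithelial-like cells, and free RNA was not separated from expression. Lipid transport genes were lower in 10 of 13 with a median of -1.61 (-1.95 to -1.23), and Fabp1 stood at 12.7% of its epithelial-like level in the Mlkl-null library. Goblet cell genes were higher in 6 of 8 with a median of 1.17 (0.83 to 1.64), and Tff3 stood at 12.8% of its epithelial-like level in the Casp8-mutant library. All 5 haemoglobin genes were higher, with a median of 4.49 (3.89 to 5.07). Enteroendocrine genes had a median of 1.42, and the remaining lists with at least 3 measured members had medians between -0.26 (brush border) and 0.46 (junction). In cluster 15 alone, a choice made after the data were seen, the medians were 1.17 for inflammasome genes, -0.77 for NF-kB targets, 0.47 for mitochondrially encoded genes, -0.99 for immediate-early genes, 5.56 for fetal or regenerative genes and 3.42 for haemoglobin genes. In the whole class the NF-kB median was 0.12 and the mitochondrial one -0.01. The log2 ratio of Zbp1 was 0.58 in the class and 2.13 in cluster 15.

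Over all retained cells together, the comparison asked which differences were large enough to show without sorting cells into classes. The antimicrobial gene Reg3g had 19 and 4714 UMIs (574-fold, 377 to 979), Ly6a 17 and 2286 UMIs (310.0-fold, 199 to 549), Ubd 0 and 232 UMIs and Reg3b 213 and 10511 UMIs (117-fold, 102 to 135). The albumin gene Alb (4 and 590 UMIs) followed a hepatocyte-like cluster of 0 and 7 cells, where 0 of 1434 cells allows a share of up to 0.257%, against 0.802% (0.323 to 1.65). The genes named as lower were Fabp1 (76662 and 760 UMIs, 42.5-fold, 39.6 to 45.7), Mme (500 and 1 UMIs), Nr2e3 (458 and 1 UMIs), Leap2 (951 and 6 UMIs) and the lipase gene Cel (382 and 1 UMIs), which stood at 1.10% of its pancreatic acinar-like level. Interferon-stimulated genes were higher in 32 of 32 with a median of 4.06 (3.99 to 4.31), and lipid transport genes lower in 17 of 18 with a median of -1.94 (-2.01 to -1.87).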

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

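No paired analysis was possible because there was 1 sample per group, and for the same reason no sample could be left out. The interferon-stimulated, MHC class I, lipid transport and brush border medians of epithelial-like cells kept their direction in every setting run. Named genes kept their direction and at least 1.5-fold in every setting run for their class, except 1 of 24 in fibroblast-like cells under the mean of per-cell shares. In fibroblast-like cells they were not run under the stricter filter or with doublets kept, where the class shrank to 9 and 18 and to 9 and 27 cells. Of the alternatives to the main class shares, 40 of 56 stayed within the counting interval, as did 48 of 70 for the main list medians, 586 of 666 for the other lists and 875 of 980 for single genes. Settings in which a class did not form were left out of these counts. For granulocyte-like cells these were the stricter filter, resolution 0.5, thinning and each library clustered alone. Their other settings were judged against a wide interval of the share ratio, 5.55 to 1427. The planned equal weighting of the original epithelial clusters was not run, since most held cells of 1 library only. Fibroblast-like cells formed no class after thinning, so no value was given there. All values that follow are log2 ratios, and the cause was not tested unless stated.

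The epithelial share, -0.27 as reported, was -0.42 with no filter, -0.0396 under the stricter filter and -0.0350 after thinning. Under the earliest naming form, chosen as an alternative after seeing the data, it was -0.0254 with no filter and -0.75 under the stricter filter. With that form it reversed to 0.0601 with doublets kept, 0.16 at resolution 0.5 and 0.17 after thinning, where it left 339, 341 and 183 Mlkl-null cells unnamed. The direction of the epithelial share therefore depended on the naming rule. In either naming form the enteric neuron share, -1.52, was -0.45 at resolution 2 and -5.85 with each library clustered alone, and the myeloid share, 1.55, was 0.95 under the stricter filter and 0.80 after thinning. The share of cells with proliferation transcripts, 1.54, was 0.80 without thinning.

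Among epithelial-like list medians, scaling by the median of ratios gave 5.35 for interferon-stimulated, 2.17 for MHC class I, -1.73 for lipid transport and -1.15 for brush border genes, which its uniform shift explains, and moved Pycard over all cells to 0.0229. A total without mitochondrial, haemoglobin and ribosomal genes gave 2.08 for MHC class I and -1.82 for lipid transport. The mean of per-cell shares gave 2.24, -1.47 and, for brush border, -0.94, and the stricter filter 1.64, -2.27 and -1.71, where Hba-x reversed to -0.48. With no minimum of UMIs, MHC class I was 2.24, and in myeloid-like cells the inflammasome median reversed to -0.0487 and the fetal or regenerative one to -0.0209, since members with few counts entered. Alternatives chosen after seeing the data included re-clustered epithelial groups weighted alike, which gave 5.71 for interferon-stimulated, 2.57 for MHC class I, -0.98 for lipid transport and -0.46 for brush border genes and reversed the junction median to 0.0695. Without clusters 4 and 18 the interferon-stimulated median was 4.79 and the MHC class I median 1.66. The brush border median was -1.17 with the endocrine-marker cluster added and -1.21 without X and Y genes, and the antimicrobial median was 7.25 without members under 25% of another class.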

Other observations

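Cell types without a cluster of their own were looked for by marker genes, as cells with 3 or more markers. Mesothelial markers were found in 9 and 15 cells, or 0.628% (0.287 to 1.19) of the Mlkl-null and 1.72% (0.965 to 2.82) of the Casp8-mutant library. Enteric glia markers were found in 11 and 0 cells, where 0 cells leave an interval of up to 0.422%. Pericyte markers were found in 8 and 1 cells, blood endothelial markers in 10 and 3, lymphatic endothelial markers in 2 and 1, and interstitial Cajal cell markers in 1 and 0. These numbers carry the depth gap, since shallower cells show fewer markers. Pancreatic acinar-like, islet-marker and hepatocyte-like cells are types of organs outside the gut wall.

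Genes that mark position along the gut were examined in epithelial-like cells. The bile acid genes of the ileum were higher in the Casp8-mutant library, with Fabp6 at 202 and 642 CPM, 3.17-fold higher (2.92 to 3.45), and Slc10a2 4.10-fold higher (2.29 to 7.63). The measured proximal genes were all below a ratio of 1, with the transcription factor genes Gata4 at 0.409 (0.263 to 0.598), Onecut2 at 0.272 (0.194 to 0.365) and Pdx1 at 0.421 (0.0705 to 1.24), the glucose transporter gene Slc5a1 at 0.669 (0.590 to 0.756) and the alcohol dehydrogenase gene Adh1 at 0.0685 (0.0406 to 0.104). Other distal genes did not follow as a group. Hoxb13 was at 2.58 (1.10 to 6.05), Fgf15 at 0.917 (0.475 to 1.62) and Osr2 at 0.726 (0.508 to 1.004). The water channel gene Aqp8 was at 0.525 (0.258 to 0.931) and Slc37a2 at 0.0880 (0.0257 to 0.191).

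Of the tests on interferon-stimulated genes, the one on free RNA from myeloid-like cells was chosen only after the result was seen, and those on depth and on sex were written before. The pattern was the median log2 ratio of 5.17 in epithelial-like cells. Free RNA from myeloid-like cells was excluded as the cause, since interferon-stimulated genes stood at a median of 127% of their myeloid-like level and myeloid markers at 5.42%. The test on lower depth, which gave 98% of Casp8-mutant and 9.14% of Mlkl-null cells with the list at 2000 UMIs per cell, was void. Casp8-mutant cells were the shallower ones and already had the higher share without thinning, 99.8% against 28.6%, so thinning could only widen the gap. The genotype could explain the pattern, but sex, infection, litter or any other difference between the embryos stays open and untested, with 1 embryo per genotype.

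Of the tests on lipid transport and brush border genes, those on the mix of epithelial groups were chosen only after the result was seen, and the test on the distal gut was written before. With 6 re-clustered epithelial groups weighted alike, the lipid transport median went from -1.91 to -0.98 and lay below 0 in all 6 groups. Equal weights thus left part of the difference in place. They do not remove free RNA of enterocytes, and the list was also lower in fibroblast-like (median -1.34) and myeloid-like cells (-1.61). Another mix of these 6 groups is therefore not excluded as the whole cause. It was -2.28 (-2.41 to -2.10) and -2.92 (-3.30 to -2.81) in groups E2 and E3 but -0.42 (-0.72 to -0.28) and -0.53 (-0.90 to -0.37) in E4 and E5. The groups paired different clusters by library, as E3 with 85 cells of cluster 6, all Mlkl-null, and 157 of cluster 19, all Casp8-mutant, so a different mix of cells within groups stays open. The brush border median went from -1.33 to -0.46 and lay below 0 in 4 of 6 groups, but only barely in E4. Another mix could therefore account for much of it and stays open. More cells from the distal gut also stays open, since the distal median lay 1.12 above the proximal one, with proximal genes at -1.29 and distal genes at -0.17, short of the rise that the test asked for. Genotype, sex and the embryo were not separated.

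The test on S100a8 and S100a9 outside granulocytes was chosen only after the result was seen. In the Casp8-mutant library S100a9 stood at 6.38% of its granulocyte-like level in epithelial-like and 5.49% in fibroblast-like cells, 1.16 times apart, and S100a8 at 9.99% and 9.45%. Myeloid-like, mixed endocrine, enteric neuron-like, lymphoid-like and erythroid-like cells carried both genes too. Over all these classes S100a9 lay between 5.49% in fibroblast-like and 10.9% in erythroid-like cells. S100a8 lay between 9.45% and 15.4% in the same 2 classes. Such similar percents in such different classes go with free RNA of granulocytes. In epithelial-like and fibroblast-like cells, however, the 2 genes lay further apart than the stated limit of 1.5, by 1.72 times in fibroblast-like cells. Free RNA as the explanation therefore stays open, and expression in each cell type was not excluded. Reg3b behaved otherwise, at 103% of its granulocyte-like level in epithelial-like and 12.9% in fibroblast-like cells. The granulocyte-like cluster thus carried as much Reg3b as the epithelium, so its barcodes may hold epithelial RNA, and this was not tested.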
